A study of Mus musculus with 16 samples.

How the data were processed

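Tcra transcripts of sorted CD3e-negative DP thymocytes were amplified from total RNA, per the labels' protocols, by template-switch RACE with a Trac primer. Each of the 16 deposited tables lists clonotypes with their V and J hits, hit scores and CDR3 nucleotide sequence. The deposited count of a clonotype is a whole number, per the file headers, and whether it counts reads or collapsed molecules is not given in the sources used here. The deposited fraction is that count divided by the total of its table, per the file headers and checked on the values. The clonotype caller, its version, its germline library, the genome build and its filters are not given in the sources used here. The tables hold no molecular identifiers.

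Groups were taken from the labels. The design text speaks of groups of 2 mice, and the labels do not say whether each library is 1 mouse. The genotype field of 12 h WT replicate 1 names the DJD allele, whereas its title and strain name WT; it was kept as WT, as titled. The loci derive from another strain than C57BL/6J, per the labels, while positions and gene identifiers come from GENCODE M21 on GRCm38, the C57BL/6J reference, so strain differences in copy number stay open.

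Because PCR copies are not independent molecules, the unit was the distinct rearrangement: a V segment, J segment and CDR3 nucleotide sequence, with the first listed hit. Per library 67.5% to 82.6% of clonotypes listed more than 1 V hit, and 4.09% to 11.5% had V hits tied in score, so near-identical copies such as Trav14-3 and its d copies are uncertain. Clonotypes without a CDR3 (0.608% to 1.67%) and those with a V or J of another chain (0.110% to 1.16%) were left out of the Trav-Traj totals. Rearrangements had a mean deposited count of 3.03 to 17.6, and those with a count of 1 made up 2.59% to 34.8%. A share of 0 allows up to 0.000584% to 0.00384% of a library (3 rearrangements). Intervals are exact Clopper-Pearson intervals at 95%, and these and the floors cover counting error only. Libraries of a group shared 10.5% to 15.7% of the smaller library's rearrangements. Libraries of different groups shared 7.73% to 18.4%, so none was a copy of another, and overlap did not set groups apart.

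Segments with at least 10 rearrangements in at least 2 libraries were tested: 86 of 88 Trav, of which 85 could be placed on the annotation, and 46 of 49 Traj. Usage was tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, the quasi-likelihood test) over all 16 libraries and 8 groups, with all Trav-Traj rearrangements as library size and no TMM factor, at a Benjamini-Hochberg adjusted p below 0.05. A log2 fold change is deleted minus control, and its SE is its size over the square root of F. Pairs of V and J regions were tested likewise. Intervals between Trav15-dv6 members, V regions and J regions were tested with limma 3.58.1 on log2 shares, adjusted over the 5 intervals, 4 V regions or 3 J regions of a comparison, with an interval SE pooled over all intervals. The intervals and this use of limma were chosen after the data were seen; regions, lists, tests and naming rule were fixed before the data were examined. Adjusted p-values in the report are from edgeR unless limma is named, and those of intervals, J regions and V regions from limma. Entropy of V-J pairs was computed after thinning, with a two-sided exact permutation test. On simulated data for DJD against WT with 86 segments of which 20 were changed, edgeR recovered 0% at 1.3-fold, 55% at 1.5-fold with 1 false call, and 95% at 2-fold with 2 false calls. The simulation drew segments independently, and apart from the changes all libraries had the WT shares. Segments of real libraries may shift together, so these rates may not hold for the data.

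Segments named in the report were the Trav15-dv6 members, the target of each deletion, the 6 Trav and 4 Traj with the largest rise and fall among those passing, with a mean share of at least 0.2% and groups that do not overlap, and the 3 Trav most used in controls. Segments given otherwise were chosen after their values were seen. Lists were the family, d copies, n copies (0 of which were listed as a first hit), the proximal list, dv segments, the TEA list and the V and J regions. Alternatives were TMM, DESeq2 1.42.0, no count minimum, deposited counts, a count of at least 2, single hits only, in-frame or out-of-frame rearrangements, only the libraries compared, a replicate block, summed paralog copies, pooled TcrdCreER controls, each replicate left out, and, added after the data were seen, tied V hits left out and a crossed block. Where a replicate was left out the lone library of its group was assumed to vary like the other groups. R 4.3.3, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.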

Results

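The Tcra repertoire was sequenced from pre-selection CD4+CD8+ double-positive (DP) mouse thymocytes, sorted as CD3e-negative, in which Trav segments join Traj segments. The 16 libraries formed 8 groups of 2. Mice lacking the D and J segments of Tcrd (DJD) were compared with wild type (WT), first at steady state and then in cells carrying the ZsGreen label 12 h after 1 mg of tamoxifen, in mice that also carried a TcrdCreER-CaM allele. Mice with a deletion of a single Trav15-dv6 family member, Trav15d-1-dv6d-1 or Trav15-1-dv6-1, were compared with TcrdCreER controls of their own. Mice were 4 to 5 weeks old. Deposited counts totalled between 1122604 and 2862941 per library, and distinct Trav-Traj rearrangements numbered between 78184 and 513756. Shares are percentages of the distinct rearrangements of a library, as mean ± SD with n = 2 libraries. Nothing in the labels ties a library to a single mouse, so p-values measure the spread between these libraries, which may be technical.

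The Trav15-dv6 members serve both Tcra and Tcrd. Their annotated V genes lie on chromosome 14 of GRCm38 at 52863299 to 52863936 (Trav15d-1-dv6d-1, ENSMUSG00000096653.4), 52956782 to 52957400 (Trav15d-2-dv6d-2, ENSMUSG00000105953.1), 53559632 to 53560247 (Trav15-1-dv6-1, ENSMUSG00000094016.2) and 53649404 to 53649994 (Trav15-2-dv6-2, ENSMUSG00000076848.3). From the distal end to the end next to the Traj array they bound intervals of 23, 7, 27, 6 and 18 other tested segments. The array was also divided into runs of neighbouring segments, V1 (the 22 most distal), V2, V3 and V4 (the 21 most proximal), and Traj into J5 (Traj61 to Traj48, the 5' end), Jmid and J3 (Traj24 to Traj2).

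The comparison of DJD with WT asked how the Tcra repertoire forms without Tcrd rearrangement to D and J segments. In DJD thymocytes distal Trav segments were used less and proximal segments more. The share of segments distal of Trav15d-1-dv6d-1 went from 27.6% ± 0.120 to 15.1% ± 0.859 (log2 fold change -0.88 ± 0.11 SE, adjusted p = 6.23e-09), and the share proximal of Trav15-2-dv6-2 from 15.8% ± 0.291 to 26.7% ± 0.412 (log2 fold change 0.76 ± 0.11 SE, adjusted p = 8.50e-08), by limma. Interval p-values here and below rest on an SE pooled over intervals of the same libraries and are too small. V1, nearly the same distal segments without that pooled SE, gave -0.92 ± 0.12 SE (adjusted p = 0.000110, limma). Trav1, the most distal segment, went from 2.96% ± 0.247 to 1.01% ± 0.0388 (log2 fold change -1.56 ± 0.40 SE, adjusted p = 0.00761) and Trav21-dv12, the most proximal, from 1.5% ± 0.0595 to 2.99% ± 0.504 (log2 fold change 0.99 ± 0.16 SE, adjusted p = 0.000824), by edgeR.

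Between Trav15d-2-dv6d-2 and Trav15-1-dv6-1 the share gave a log2 fold change of 0.01 ± 0.11 SE (adjusted p = 0.922). Between Trav15d-1-dv6d-1 and Trav15d-2-dv6d-2 it was -0.31 ± 0.11 SE (adjusted p = 0.0103) and between Trav15-1-dv6-1 and Trav15-2-dv6-2 0.35 ± 0.11 SE (adjusted p = 0.00582). Without DJD replicate 1 neither of the last calls held, at -0.27 and 0.30 (adjusted p = 0.0912 and 0.0778), and without WT replicate 2 the former did not, at -0.28 (adjusted p = 0.0786). With single V and J hits only neither held, at -0.10 and 0.46 (adjusted p = 0.715 and 0.223).

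Of 86 Trav segments 18 rose and 18 fell in DJD by edgeR. All 18 that fell were among the 22 of V1, and 17 of those that rose among the 21 of V4. Adjusted over the list alone, 20 fell in V1, 20 rose in V4, and 0 of 21 changed in V2 and 0 of 21 in V3, where 1 had risen over all segments. V3 as a whole went from 31.9% ± 0.0223 to 34.3% ± 0.550 (log2 fold change 0.10 ± 0.04 SE, adjusted p = 0.0239), by limma. Trav2 fell by 1.45 ± 0.22 SE on the log2 scale (adjusted p = 0.000824), and Trav5-1, Trav6-2, Trav6-1 and Trav7-1 fell by 1.21 ± 0.25, 1.20 ± 0.32, 1.14 ± 0.26 and 1.08 ± 0.26. Trav14-3, Trav3-4, Trav19, Trav17 and Trav13-4-dv7 rose by 0.97 ± 0.26, 0.94 ± 0.18, 0.93 ± 0.17, 0.92 ± 0.29 and 0.90 ± 0.19. Trav14-3 did not pass once clonotypes with tied V scores were left out (adjusted p = 0.120). Trav7-3 and Trav14-1, with Trav1 the most used WT segments, gave -0.07 ± 0.12 and 0.22 ± 0.09 SE (adjusted p = 0.747 and 0.0594).

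No Trav15-dv6 member passed in DJD, also when adjusted over the list alone (0 of 4), whereas DESeq2 called 2 higher and TMM 1. In WT and DJD Trav15d-1-dv6d-1 held 0.786% ± 0.0640 and 0.677% ± 0.0705, Trav15d-2-dv6d-2 0.497% ± 0.0140 and 0.513% ± 0.0515, Trav15-1-dv6-1 0.642% ± 0.0286 and 0.780% ± 0.120 and Trav15-2-dv6-2 0.680% ± 0.0482 and 1.06% ± 0.153. The adjusted p-values were 0.458, 0.922, 0.394 and 0.0594. Of the proximal list (Trav17 to Trav21-dv12) 4 of 5 rose, 5 adjusted over the list alone. Of the 36 segments with a d copy letter 11 fell, 10 adjusted over the list alone. Of the 10 dv segments, which also serve Tcrd, 4 rose, 4 adjusted over the list alone. The 36 changed segments became 14 with single V and J hits only (8 higher and 6 lower), 23 with paralog copies summed, 48 with a replicate block (25 higher and 23 lower), and 21, 16 and 18 without WT replicate 1, WT replicate 2 or DJD replicate 1. Single hits left 57 segments tested and summed copies 50, in place of 86, so these counts are no measure of calls lost. By DESeq2 25 rose and 16 fell, with the median log2 fold change at 0.14 in place of -0.06.

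**Figure D1:**
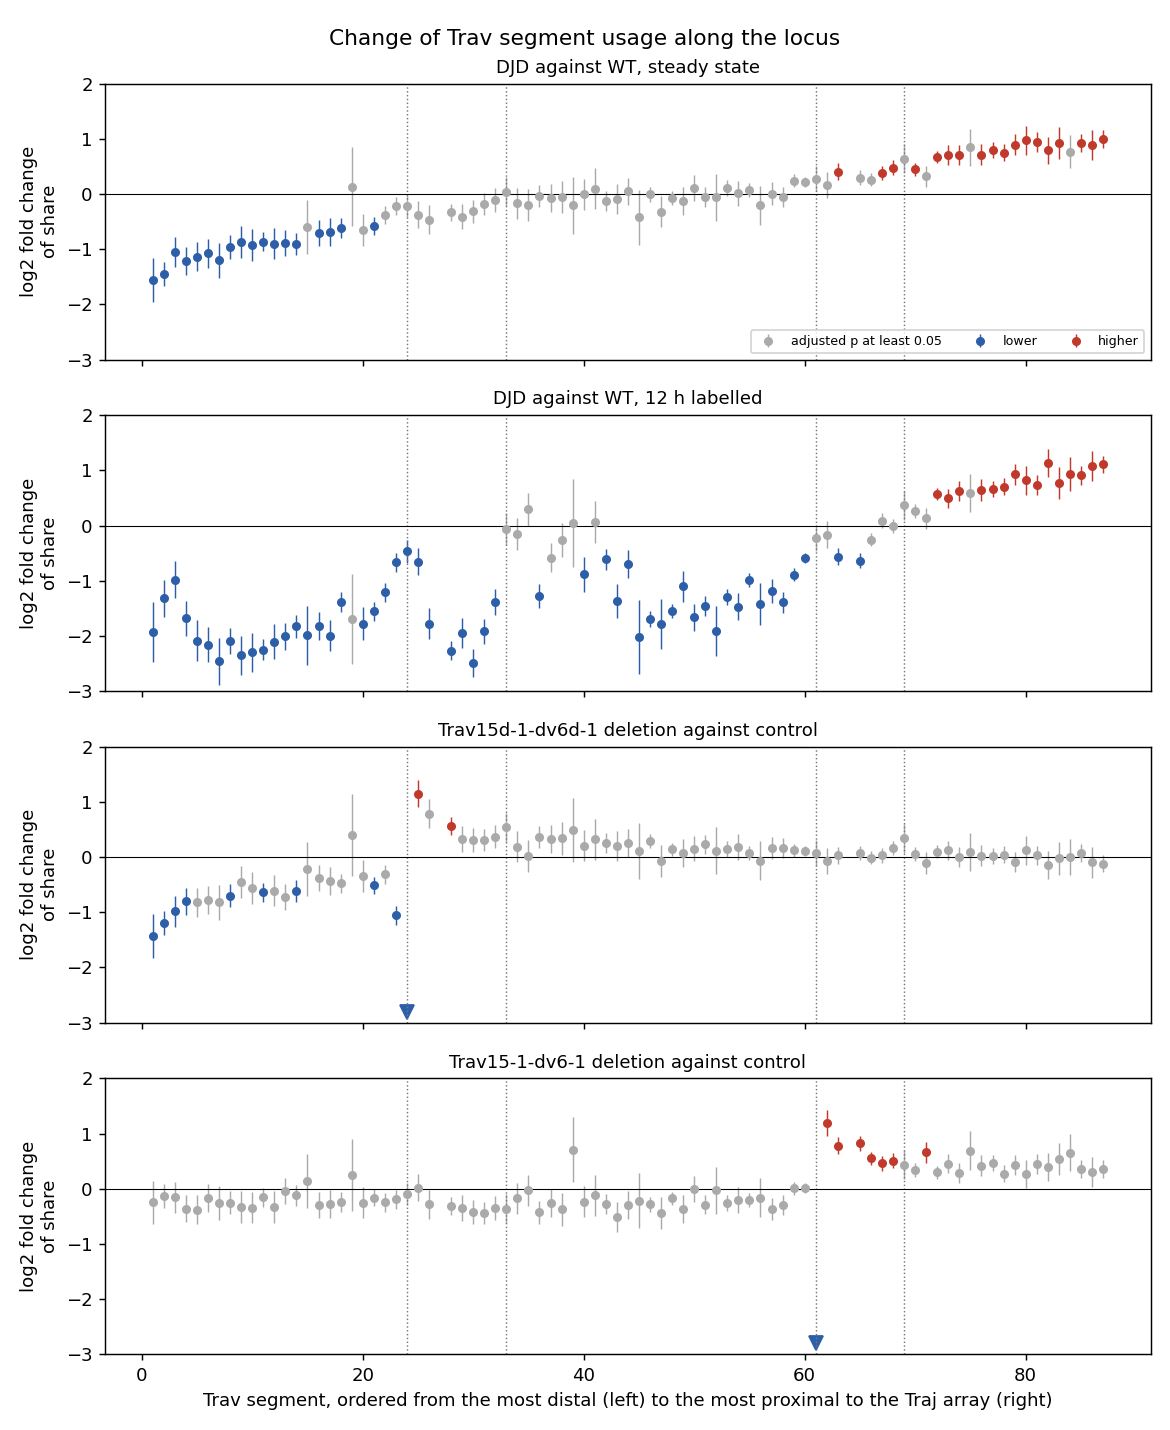
Log2 fold change of each Trav segment's share (y axis; points, with SE bars) by its order along the array from distal to proximal (x axis) in the 4 comparisons, in red or blue where edgeR's test passed, with dotted lines at the Trav15-dv6 members. Triangles are the deleted segments, off the scale at -8.27 and -6.47; in DJD the 18 segments that fell lie at the distal end, and at 12 h the direction of many V2 and V3 segments flips with DESeq2 scaling.

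Over all Trav together, Traj usage gave no call in DJD, but the Traj that a Trav had joined did change. Among V3 rearrangements J5 made up 20.4% ± 0.678 in WT and 9.29% ± 0.145 in DJD, and J3 31.1% ± 1.55 and 44.5% ± 0.623. Of 12 pairs of V and J regions 4 rose and 5 fell (edgeR). V1 with J5 went from 2.16% ± 0.166 to 0.547% ± 0.0469 (log2 fold change -1.98 ± 0.15 SE, adjusted p = 1.71e-07) and V3 with J5 from 6.52% ± 0.221 to 3.19% ± 0.00145 (log2 fold change -1.03 ± 0.11 SE, adjusted p = 3.52e-06). V4 with J3 and V3 with J3 rose by 0.94 ± 0.11 and 0.62 ± 0.13 SE on the log2 scale. Of 46 Traj segments 0 passed by edgeR and 0 by DESeq2, with 1 at an unadjusted p under 0.05 by edgeR, but 13 passed when only these libraries were fitted. Adjusted over the list alone, 1 of 5 Traj under control of the TEA promoter (Traj61 to Traj53) fell, and 0 of 9 changed in J5, 0 of 20 in Jmid and 0 of 17 in J3.

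DJD was then compared with WT 12 h after labelling, in mice that also carried the TcrdCreER-CaM allele, when joins lay mostly in J5 (67.4% ± 0.707 against 19.4% ± 0.662 in steady-state WT). Proximal Trav segments took most of the 12 h DJD repertoire. The share proximal of Trav15-2-dv6-2 went from 39.8% ± 1.19 to 66.8% ± 3.12 (log2 fold change 0.75 ± 0.11 SE, adjusted p = 6.80e-08), by limma. The share distal of Trav15d-1-dv6d-1 went from 12.5% ± 0.0142 to 4.25% ± 0.541 (log2 fold change -1.56 ± 0.11 SE, adjusted p = 1.48e-16) and that between Trav15d-1-dv6d-1 and Trav15d-2-dv6d-2 from 3.56% ± 0.00360 to 1.03% ± 0.101 (log2 fold change -1.79 ± 0.11 SE, adjusted p = 2.83e-18). Trav21-dv12, the most used segment, went from 5.59% ± 0.0444 to 12.1% ± 0.645 (log2 fold change 1.11 ± 0.16 SE, adjusted p = 2.56e-05), by edgeR.

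Between Trav15d-2-dv6d-2 and Trav15-1-dv6-1 the 12 h share went from 28.2% ± 0.915 to 14.3% ± 2.00 (log2 fold change -0.98 ± 0.11 SE, adjusted p = 1.12e-10). Between Trav15-1-dv6-1 and Trav15-2-dv6-2 the log2 fold change was -0.25 ± 0.11 SE (adjusted p = 0.0328), a call that ended without either 12 h WT library, without 12 h DJD replicate 1 or without clonotypes with tied V scores, at -0.25, -0.24, -0.23 and -0.20 (adjusted p = 0.0945, 0.103, 0.0722 and 0.0774).

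As shares of the repertoire 15 Trav segments rose and 53 fell at 12 h (edgeR). Scaling moved this split to 28 and 30 with TMM and 39 and 16 with DESeq2, as the median log2 fold change moved from -0.98 to -0.15 and 0.26. V4 rose and V1 fell under each scaling: 15, 21 and 21 of 21 V4 segments were higher and 21, 17 and 12 of 22 V1 segments lower as shares, with TMM and with DESeq2. In V2 and V3, 14 and 18 of 21 each fell as shares, but with DESeq2 11 and 6 rose and 4 and 0 fell. Adjusted over the list alone, 21 fell in V1, 13 in V2 and 18 in V3, and 15 rose in V4.

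Trav19, Trav14-3 and Trav13-4-dv7 rose at 12 h by 0.91 ± 0.17, 0.82 ± 0.26 and 0.93 ± 0.19 SE on the log2 scale, and Trav13-5 and Trav20 by 1.13 ± 0.25 and 1.08 ± 0.28. Trav12d-2 of V2 went from 1.25% ± 0.0915 to 0.259% ± 0.0346 (log2 fold change -2.27 ± 0.17 SE, adjusted p = 2.27e-07), by edgeR. Trav7d-3, Trav7d-2, Trav7d-4 and Trav10d of V1 fell by 2.25 ± 0.19, 2.09 ± 0.24, 2.01 ± 0.25 and 2.00 ± 0.28. Trav9-1 fell by 1.91 ± 0.46 as a share but did not pass with TMM or DESeq2 (adjusted p = 0.0576 and 0.223). Trav14-1, one of the most used in 12 h WT, gave -0.59 ± 0.09 SE as a share and 0.69 with DESeq2.

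In 12 h WT and DJD Trav15d-1-dv6d-1 held 0.697% ± 0.0521 and 0.503% ± 0.0734 (log2 fold change -0.47 ± 0.20 SE, adjusted p = 0.0464, edgeR), with 0.80 by DESeq2, the opposite direction. Trav15-1-dv6-1 and Trav15d-2-dv6d-2 gave -0.23 ± 0.24 and -0.06 ± 0.28 SE as shares (adjusted p = 0.384 and 0.857) and 1.05 and 1.20 by DESeq2. Trav15-2-dv6-2 gave 0.37 ± 0.26 SE (adjusted p = 0.208) and 1.64 by DESeq2. Adjusted over the list alone 0 members changed. All 5 of the proximal list rose, with 5 adjusted over the list alone. Of the 36 d copies 28 fell, 28 adjusted over the list alone, while DESeq2 called 11 higher and 13 lower. Of the 10 dv segments 4 rose and 3 fell as shares (4 and 2 adjusted over the list alone), and 10 rose by DESeq2. Single V and J hits left 57 tested and 24 changed segments, 1 higher and 23 lower. With summed paralog copies 43 of 50 changed.

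**Figure D2:**
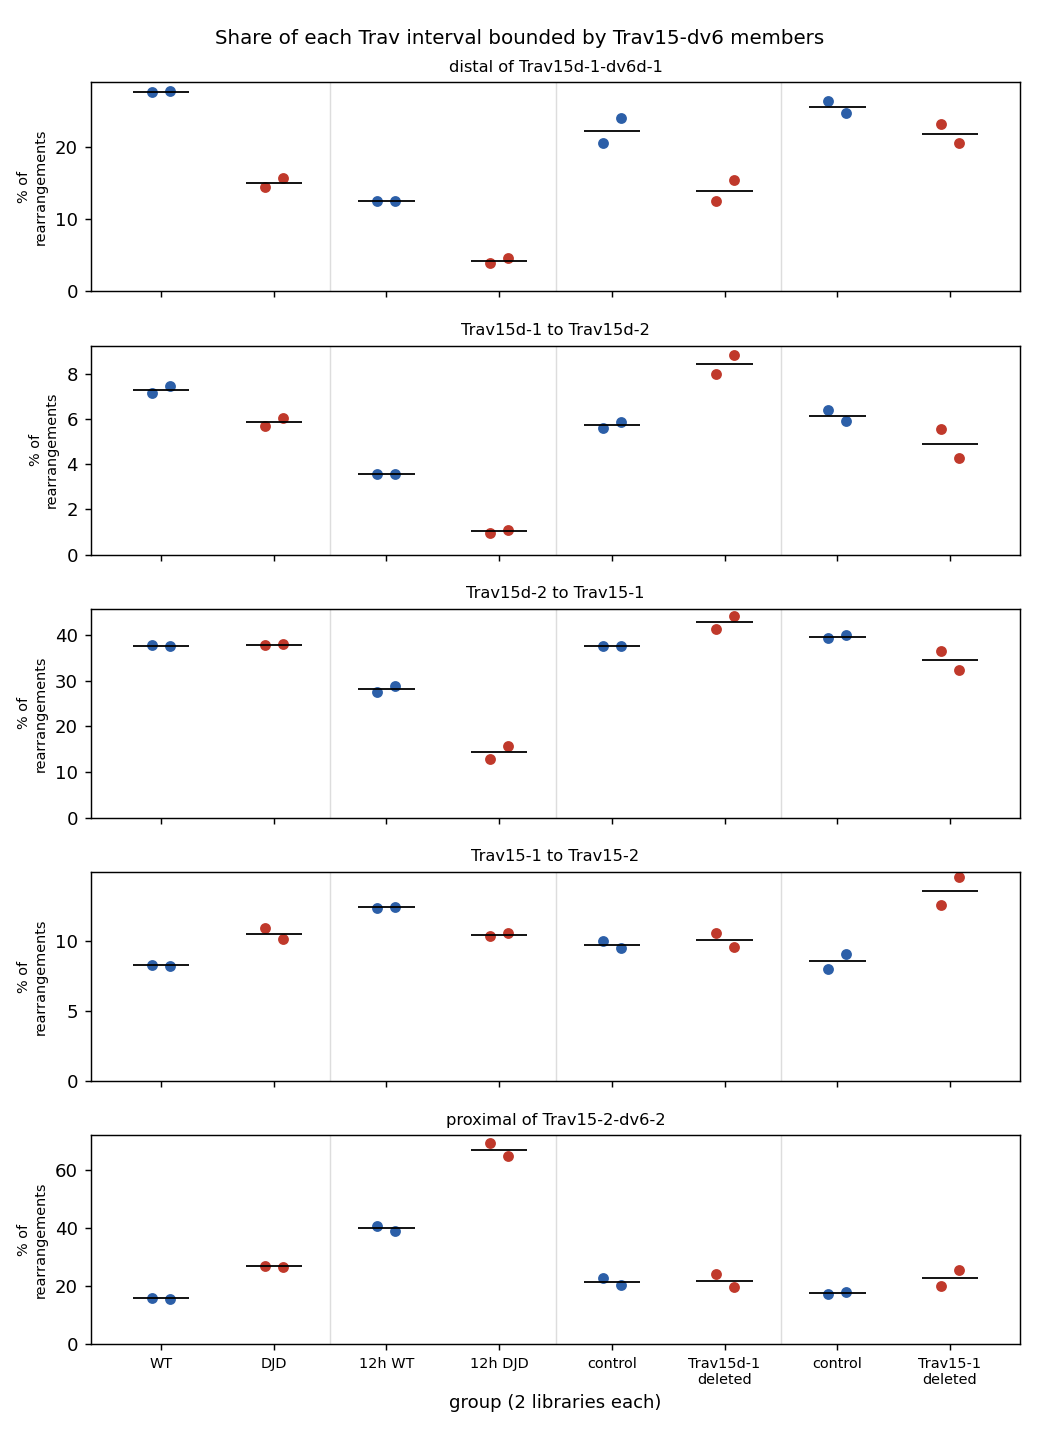
Share of distinct rearrangements (%, y axis) in each Trav interval bounded by Trav15-dv6 members for the 8 groups (x axis), with points for libraries and lines for group means. Proximal of Trav15-2-dv6-2 the 12 h DJD libraries stand at 69.0% and 64.6% and the 12 h WT libraries at 40.7% and 39.0%.

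Traj58, within the TEA list, went from 10.9% ± 0.181 to 5.21% ± 0.609 (log2 fold change -1.06 ± 0.20 SE, adjusted p = 0.00120) in 12 h DJD, by edgeR, and Jmid as a whole from 27.5% ± 0.203 to 36.1% ± 1.25 (log2 fold change 0.39 ± 0.07 SE, adjusted p = 0.000437), by limma. J3 went from 4.14% ± 0.894 to 5.33% ± 0.445 (log2 fold change 0.38 ± 0.15 SE, adjusted p = 0.0363, limma). J5 as a whole did not pass, at 67.4% ± 0.707 and 57.8% ± 1.76 (log2 fold change -0.22 ± 0.11 SE, adjusted p = 0.0635, limma). Of 46 Traj segments 20 rose and 2 fell as shares, but 0 rose and 8 fell with TMM and 0 and 21 with DESeq2, the median log2 fold change moving from 0.36 to -0.06 and -0.35. Traj30, Traj26, Traj16 and Traj31 rose as shares by 0.66 ± 0.12, 0.66 ± 0.11, 0.58 ± 0.15 and 0.58 ± 0.10 SE and gave -0.06, -0.06, -0.14 and -0.13 with DESeq2. Of the TEA list 2 of 5 fell, 2 adjusted over the list alone. Adjusted over the list alone, 1 of 9 in J5 fell and 15 of 20 in Jmid and 5 of 17 in J3 rose as shares, with 0 and 0 higher under TMM. Without 12 h WT replicate 2 or 12 h DJD replicate 1, 13 and 14 Traj segments passed. Of the region pairs 3 rose and 7 fell, and 7 and 3 with TMM. V4 with Jmid rose by 1.10 ± 0.12 SE and V1 with J5 fell by 1.86 ± 0.15 SE.

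Labelled and steady-state WT cells differed too, with 27 Trav segments higher and 35 lower at 12 h by edgeR (31 and 31 with TMM). V4 held 44.8% ± 0.995 against 18.9% ± 0.373 and V1 11.4% ± 0.0692 against 26.4% ± 0.00230. The 12 h mice differed also in Tcra-Tcrd alleles and tamoxifen, so time and genotype cannot be separated. The genotype field of 12 h WT replicate 1 names the DJD allele and its title and strain name WT. That library held 65 rearrangements ending in Trdj1, a segment deleted in DJD, and without it 63 Trav segments changed between 12 h DJD and WT in place of 68.

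The deletion of Trav15d-1-dv6d-1 asked what a single distal family member contributes. Trav15d-1-dv6d-1 itself went from 0.630% ± 0.0129 to 0.00204% ± 0.000465 (log2 fold change -8.27 ± 0.32 SE, adjusted p = 3.05e-11), by edgeR, with 5 rearrangements left in each knockout library. The share of segments distal of the deletion fell and that of segments just proximal of it rose. Distal of Trav15d-1-dv6d-1 it went from 22.3% ± 2.44 to 13.9% ± 2.04 (log2 fold change -0.68 ± 0.11 SE, adjusted p = 1.65e-06), and up to Trav15d-2-dv6d-2 from 5.73% ± 0.210 to 8.40% ± 0.620 (log2 fold change 0.55 ± 0.11 SE, adjusted p = 3.67e-05), by limma. With single V and J hits only the latter did not pass, at 0.63 (adjusted p = 0.0687). Toward the Traj array the log2 fold changes of the other intervals were 0.19 ± 0.11 SE (adjusted p = 0.176), 0.04 ± 0.11 SE (adjusted p = 0.838) and 0.02 ± 0.11 SE (adjusted p = 0.838).

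In these knockouts 2 Trav segments rose and 10 fell (edgeR). Trav9d-2, the first tested segment proximal of the deletion, went from 0.222% ± 0.0222 to 0.490% ± 0.130 (log2 fold change 1.15 ± 0.24 SE, adjusted p = 0.00708). Trav12d-2 rose by 0.57 ± 0.16 SE on the log2 scale (adjusted p = 0.0364). Trav14d-1, the nearest distal segment, went from 1.15% ± 0.0727 to 0.554% ± 0.00960 (log2 fold change -1.05 ± 0.17 SE, adjusted p = 0.00130). Trav1, Trav2, Trav3-1 and Trav5-1 at the distal end fell by 1.43 ± 0.40, 1.20 ± 0.22, 0.98 ± 0.28 and 0.80 ± 0.25 SE (adjusted p = 0.0364, 0.00237, 0.0377 and 0.0487). Trav15d-2-dv6d-2, Trav15-1-dv6-1 and Trav15-2-dv6-2 gave 0.54 ± 0.26, 0.07 ± 0.23 and 0.34 ± 0.26 SE (adjusted p = 0.233, 0.929 and 0.519). Trav7-3, Trav14-1 and Trav7-4, the most used in controls, gave 0.14 ± 0.12, 0.11 ± 0.09 and 0.16 ± 0.23 SE (adjusted p = 0.559, 0.519 and 0.808).

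Of V1, 8 of 22 segments fell in these knockouts, 13 adjusted over the list alone. Of V2, 2 rose and 2 fell (3 and 2 adjusted over the list alone), and of V3 and V4 0 changed either way. V3 as a whole went from 34.4% ± 0.224 to 37.5% ± 0.592 (log2 fold change 0.12 ± 0.04 SE, adjusted p = 0.0144), by limma. Of the d copies 2 rose and 6 fell (3 and 7 adjusted over the list alone). In the family and the dv segments the target alone changed, also adjusted over the list alone, and 0 of the proximal list did. No Traj segment passed by edgeR, with 0 of 46 at an unadjusted p under 0.05 and 0 by DESeq2, and 0 in the TEA list, J5, Jmid or J3 adjusted over the list alone. V1 with J5 and V1 with Jmid, the 2 region pairs that changed, fell by 1.41 ± 0.15 and 0.87 ± 0.14 SE. The 12 changed Trav segments became 3 without control replicate 2, 4 without knockout replicate 1, 4 when only these libraries were fitted, 2 with single V and J hits, 7 with paralog copies summed, 21 with all TcrdCreER controls pooled and 20 with a replicate block (4 higher and 16 lower).

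The deletion of Trav15-1-dv6-1 did the same for a proximal member. Trav15-1-dv6-1 went from 0.504% ± 0.0679 to 0.00576% ± 0.00311 (log2 fold change -6.47 ± 0.33 SE, adjusted p = 1.31e-09), by edgeR, with 17 and 9 rearrangements left. The share of segments just proximal of the deletion rose. Between Trav15-1-dv6-1 and Trav15-2-dv6-2 it went from 8.54% ± 0.742 to 13.6% ± 1.41 (log2 fold change 0.67 ± 0.11 SE, adjusted p = 2.56e-06), by limma. Trav9-2, the first tested segment proximal of the deletion, went from 0.267% ± 0.00551 to 0.608% ± 0.0286 (log2 fold change 1.19 ± 0.24 SE, adjusted p = 0.00457), by edgeR.

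The share proximal of Trav15-2-dv6-2 went from 17.6% ± 0.415 to 22.8% ± 4.03 (log2 fold change 0.36 ± 0.11 SE, adjusted p = 0.00647) and that between Trav15d-1-dv6d-1 and Trav15d-2-dv6d-2 from 6.13% ± 0.337 to 4.90% ± 0.927 (log2 fold change -0.33 ± 0.11 SE, adjusted p = 0.00780). Neither call held without control replicate 1, at log2 fold changes of 0.34 and -0.28 (adjusted p = 0.0605 and 0.0968) or without knockout replicate 2, at 0.18 and -0.14 (adjusted p = 0.283 and 0.283), nor with single V and J hits only, at 0.42 and -0.24 (adjusted p = 0.0796 and 0.401). The share distal of Trav15d-1-dv6d-1 gave a log2 fold change of -0.23 ± 0.11 SE (adjusted p = 0.0610) and that between Trav15d-2-dv6d-2 and Trav15-1-dv6-1 -0.20 ± 0.11 SE (adjusted p = 0.0757), which both passed without knockout replicate 1 (adjusted p = 0.0123 and 0.0154).

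In the Trav15-1-dv6-1 knockouts 7 Trav segments rose and the target alone fell (edgeR). Trav12-2 rose by 0.82 ± 0.13 SE on the log2 scale, Trav4-3 by 0.78 ± 0.15, Trav12-3 by 0.55 ± 0.12 and Trav14-2 by 0.51 ± 0.13. Trav9-4 rose by 0.66 ± 0.19 (adjusted p = 0.0447) but gave -0.56 with single V and J hits only. Trav15d-1-dv6d-1, Trav15d-2-dv6d-2 and Trav15-2-dv6-2 gave -0.10 ± 0.20, -0.36 ± 0.26 and 0.43 ± 0.26 SE (adjusted p = 0.727, 0.352 and 0.314). Trav7-3, Trav14-1 and Trav6-6, the most used in controls, gave -0.18 ± 0.12, 0.01 ± 0.09 and -0.21 ± 0.13 SE (adjusted p = 0.324, 0.957 and 0.314).

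Of V3, 4 rose and 1 fell, and of V4 3 rose (4, 1 and 4 adjusted over the list alone). Of V1, V2, the d copies and the proximal list 0 changed, also adjusted over the list alone, and in the family and dv segments the target alone did. No Traj segment passed by edgeR, with 5 of 46 at an unadjusted p under 0.05 and 0 by DESeq2, and 0 in the TEA list, J5, Jmid or J3 adjusted over the list alone. No region pair passed by edgeR, with 4 of 12 at an unadjusted p under 0.05 and 0 by DESeq2. The 8 changed Trav segments became 2 and 4 without control replicate 1 or 2, 17 and 5 without knockout replicate 1 or 2, 4 when only these libraries were fitted, 1 with single V and J hits, 4 with paralog copies summed and 18 with a replicate block (14 higher and 4 lower). The block, for pairs that the labels do not give, also called 2 region pairs. Without knockout replicate 1, 15 Traj segments passed.

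**Figure D3:**
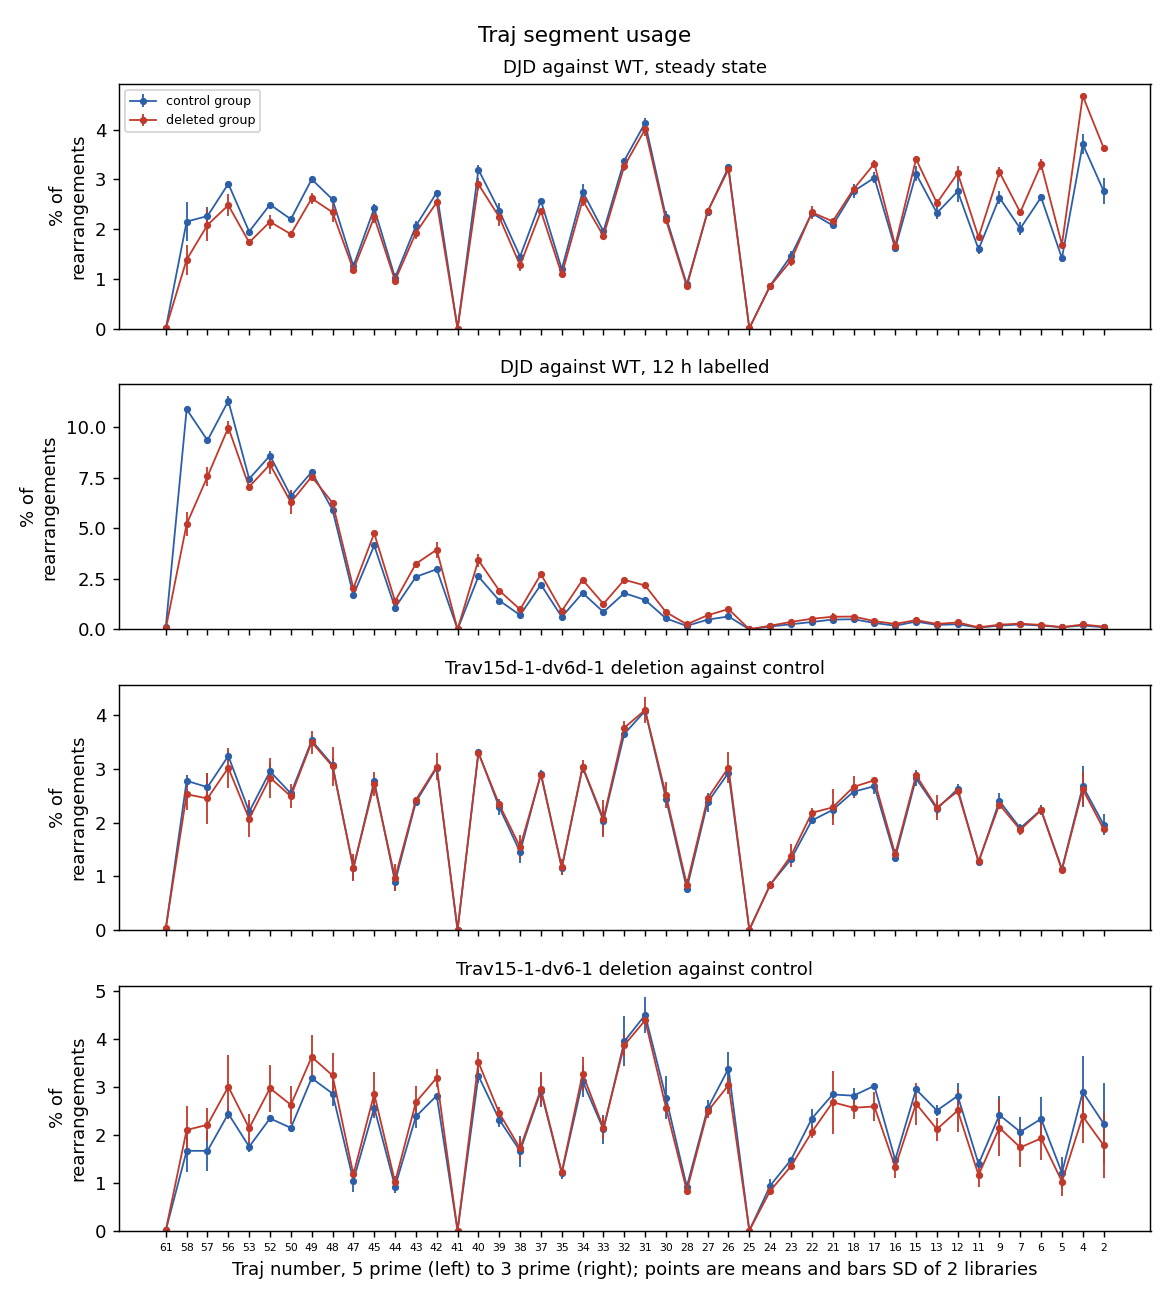
Share of distinct rearrangements (%, y axis) by Traj number from 5' to 3' (x axis) in the control (blue) and deleted (red) groups of the 4 comparisons; points are means and bars SD of 2 libraries. Traj58 stands at 10.9% in 12 h WT and 5.21% in 12 h DJD.

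The TcrdCreER controls of the Trav15d-1-dv6d-1 and Trav15-1-dv6-1 deletions carry the same genotype label and gave 0 Trav segments that differed by edgeR, with 7 of 86 at an unadjusted p under 0.05 and 0 by DESeq2. With a replicate block, for pairs that the labels do not give, 11 differed, 2 higher and 9 lower in the Trav15-1-dv6-1 controls. By limma no interval or V region passed between these controls. Proximal of Trav15-2-dv6-2 the share was 17.6% ± 0.415 in the Trav15-1-dv6-1 controls against 21.5% ± 1.78 (log2 difference -0.28 ± 0.11 SE, adjusted p = 0.0780). In size this is near the 0.36 of that interval with the Trav15-1-dv6-1 deletion. V4 gave -0.28 ± 0.11 SE (adjusted p = 0.151). J5 was lower in the Trav15-1-dv6-1 controls, 17.9% ± 0.946 against 22.8% ± 0.757 (adjusted p = 0.0221, limma), and 5 TEA and 6 J5 segments were lower adjusted over the list alone.

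V-J pair diversity, the Shannon entropy of V-J pairs after thinning to 78184 rearrangements, was lower in the mean of each deleted group. Control and deleted means were 11.19 and 10.98 bits for DJD, 10.01 and 9.61 for 12 h DJD, 11.11 and 11.02 for the Trav15d-1-dv6d-1 knockouts and 11.15 and 11.07 for the Trav15-1-dv6-1 knockouts (SD 0.0288 and 0.00801, 0.00149 and 0.0776, 0.0391 and 0.0311 and 0.0229 and 0.0662, n = 2). With each library left out in turn the difference in the Trav15-1-dv6-1 knockouts ran from -0.128 to -0.0339 bits. A two-sided exact permutation test of 2 against 2 cannot go below p = 0.33, the value in each comparison. Without thinning the entropies lay between 9.56 and 11.24 bits.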

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

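The tests of the explanations weighed here, the limma tests of intervals and the tests of Trdv segments were chosen after the results were seen, while the edgeR tests of differences between effects were planned.

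The change of Trav shares in DJD differed between 12 h and steady state. As shares, 40 Trav segments differed by edgeR (all lower at 12 h), but 3 with TMM and 25 higher and 2 lower with DESeq2, so the direction rests on the scaling. With each library left out in turn the count ran from 24 to 46. Trav14-1 gave a log2 difference of -0.81 ± 0.12 SE as a share (adjusted p = 0.000169) and -0.02 with TMM. By interval the log2 differences of shares were -0.68 ± 0.16 SE (adjusted p = 0.000172) distal of Trav15d-1-dv6d-1, -1.48 ± 0.16 SE (adjusted p = 6.64e-11) from there to Trav15d-2-dv6d-2, -0.995 ± 0.16 SE (adjusted p = 4.57e-07) on to Trav15-1-dv6-1, -0.59 ± 0.16 SE (adjusted p = 0.000682) on to Trav15-2-dv6-2 and -0.02 ± 0.16 SE (adjusted p = 0.918) proximal of Trav15-2-dv6-2, by limma.

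The 2 family deletions differed for 10 Trav segments by edgeR, 7 higher and 3 lower with the Trav15-1-dv6-1 deletion (5 and 4 by DESeq2). The count, which includes both targets, went to 2 without replicate 1 of the Trav15d-1-dv6d-1 controls, 2 without that of the Trav15-1-dv6-1 controls, 2 with single V and J hits, 2 when only these libraries were fitted and 33 with a replicate block. The targets themselves gave log2 differences of -6.54 (Trav15-1-dv6-1) and 8.17 (Trav15d-1-dv6d-1). By interval, from distal to proximal, the differences were 0.46 ± 0.16 SE (adjusted p = 0.0105), -0.89 ± 0.16 SE (adjusted p = 8.45e-06), -0.39 ± 0.16 SE (adjusted p = 0.0228), 0.62 ± 0.16 SE (adjusted p = 0.000775) and 0.34 ± 0.16 SE (adjusted p = 0.0396), by limma. In the last interval the Trav15-1-dv6-1 and Trav15d-1-dv6d-1 knockouts stood at 22.8% and 21.9%. Their controls stood at 17.6% and 21.5%, so that difference came mostly from the controls. Alternative settings were not run for these interval differences.

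Trdv segments joined to Traj, which the comparisons of Trav leave out, were more frequent in DJD. Set against all Trav-Traj rearrangements they stood at 0.108% ± 0.00785 in WT and 0.302% ± 0.0165 in DJD, and at 0.413% ± 0.0105 and 1.12% ± 0.0191 at 12 h (n = 2 each). The log2 fold changes of Trdv1, Trdv2-1 and Trdv2-2 were 1.27 ± 0.28, 1.78 ± 0.42 and 1.70 ± 0.45 SE at steady state and 1.40 ± 0.28, 1.36 ± 0.42 and 1.62 ± 0.46 SE at 12 h (largest adjusted p = 0.00835, edgeR).

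Set against all Trav-Traj rearrangements, those ending in the Trdj1 sequence stood at 0.0718% ± 0.0161 in 12 h WT against 0.0132% ± 0.00106 in steady-state WT, a difference not tested. The libraries were amplified with a Trac primer, so these shares do not measure how often Tcrd rearranged. None was seen in the DJD libraries, which allows up to 0.000814% to 0.00371% (3 counts per library).

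The tables name Trdj1 as the J of Trdv clonotypes even in libraries whose Tcrd J segments are deleted. Carry-over from libraries with an intact locus would bring CDR3s that end in the Trdj1 sequence, and 0 were found in the 4 DJD libraries. Of these CDR3s 99.1% ended in 15 nucleotides that belong to a single Traj, as a J choice limited to delta names would give. The Trdv-Traj joins above were counted by these ends. No biological explanation was tested.

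V1 and V2 shares fell in 12 h DJD. Were the rise of proximal segments alone the cause, all other shares would fall alike, but V1 over V3 fell further, with a log2 difference between groups of -0.793 (SD 0.0951). For V2 over V3 the difference was 0.075 (SD 0.301), so for V2 as a whole a fall alike with the other shares cannot be told apart from a loss of its own. Within V2 the 7 segments between Trav15d-1-dv6d-1 and Trav15d-2-dv6d-2 changed by -1.79 ± 0.11 SE, against -0.89 ± 0.04 SE for V3. Those 7 were picked after their values were seen, and their SE, pooled over intervals, is too small. The median V3 segment changed by -1.30, nearer to the 7 than V3 as a whole, so no conclusion is drawn for them. Trav15d-1-dv6d-1 and Trav15d-2-dv6d-2, also of V2, fell less than V3, at -0.47 ± 0.20 and -0.06 ± 0.28 SE. With Trav21-dv12 left out of the totals V1 changed by -1.58, in place of -1.68. Trav21-dv12 went from 5.59% to 12.1%, too small a share for its removal to move V1 much. The outcome was thus fixed by these shares, and no conclusion is drawn from it. The genotype field of 12 h WT replicate 1 is that of the 12 h DJD libraries, but 65 of its rearrangements ended in Trdj1 against 0 in each of those, which argues against that label; were it right, the library would make the fall smaller. A loss of V1 use in DJD may remain as a hypothesis, found and tested on the same libraries, and differences between the mice that the labels do not record stay open.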

How the results depend on the processing

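Settings that left out tied V hits, crossed the block or bear on intervals were chosen after the data were seen; the others were planned. Of the alternatives of single segments and intervals 1137 stayed on the same side of the threshold, 99 lost the call, 22 gained it and 13 reversed. A reversal was counted only where the main or the alternative setting passed. Changes of sign where neither passed would be among the 1137. Of counts and diversity values 226 stayed close and 59 moved.

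The causes of these moves were not tested. With single V and J hits changed Trav segments numbered 14 in DJD, 24 at 12 h, 2 and 1 with the Trav15d-1-dv6d-1 and Trav15-1-dv6-1 deletions, 32 for 12 h WT against WT, 18 and 2 for the differences of DJD and of deletion effects; Traj at 12 h numbered 8 and region pairs with the Trav15-1-dv6-1 deletion 1. Summed paralog copies gave 23, 43, 7 and 4 of 50 tested in the first 4, against 36, 68, 12 and 8 of 86 in the main fits. Fitting only the libraries compared gave 4 and 4 Trav segments with the Trav15d-1-dv6d-1 and Trav15-1-dv6-1 deletions, 2 for their difference, 13 Traj in DJD and 4 region pairs with the Trav15d-1-dv6d-1 deletion. Pooled TcrdCreER controls gave 21 Trav segments with that deletion. TMM gave 3 segments for the difference of DJD effects and 8 Traj at 12 h, and DESeq2 4 region pairs with the Trav15d-1-dv6d-1 deletion. Deposited counts and a count of at least 2 gave 6 and 6 for the difference of deletion effects. Without a count minimum 1 Traj changed in DJD, and without tied V hits 2 region pairs did with the Trav15-1-dv6-1 deletion. Entropy differences from deposited counts were -0.250 bits in DJD and -0.548 at 12 h.

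At 12 h Trav15-1-dv6-1, Trav15d-1-dv6d-1, Trav15d-2-dv6d-2 and Trav14-1 reversed to 0.62, 0.37, 0.78 and 0.26 with TMM and 1.05, 0.80, 1.20 and 0.69 with DESeq2, which shift all segments alike. Traj30, Traj26, Traj16 and Traj31 reversed to -0.0553, -0.0552, -0.14 and -0.13 with DESeq2. Trav9-4 reversed to -0.56 with single hits in the Trav15-1-dv6-1 deletion.

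Replicate numbers do not pair the libraries by the labels. Deviations of same-numbered libraries correlated at -0.60 (DJD), 0.35 (12 h), 0.90 (Trav15d-1-dv6d-1) and 0.67 (Trav15-1-dv6-1). In the Trav15d-1-dv6d-1 controls and knockouts, clonotypes without a CDR3 made up 0.608% and 0.636% of replicate 1 and 1.578% and 1.435% of replicate 2. In the Trav15-1-dv6-1 sets they made up 0.827% and 0.772%, and 1.5% and 1.539%. The main fits take no account of a batch shared by same-numbered libraries, and leaving out a replicate splits such pairs. A replicate block gave 20 and 18 Trav segments with the Trav15d-1-dv6d-1 and Trav15-1-dv6-1 deletions, 11 between their controls, 33 for their difference, 2 Traj in DJD and 2 region pairs with the Trav15-1-dv6-1 deletion. A crossed block gave 53 Trav segments and 4 Traj in DJD, against 48 and 2 with the block.

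Leaving out each replicate gave ranges of changed Trav segments of 16 to 29 in DJD, 59 to 70 at 12 h, 3 to 11 and 2 to 17 with the Trav15d-1-dv6d-1 and Trav15-1-dv6-1 deletions, 0 to 0 between controls, 53 to 56 for 12 h WT against WT, and 24 to 46 and 2 to 16 for the differences of DJD and deletion effects. For Traj they were 0 to 0, 13 to 23, 0 to 0 and 0 to 15 in the first 4, for region pairs 8 to 9, 9 to 11, 2 to 2 and 0 to 2, and for entropy -0.234 to -0.194, -0.456 to -0.346, -0.122 to -0.0673 and -0.128 to -0.0339 bits. With 2 libraries per group, simulated data for Trav in DJD, with segments drawn independently, gave back 0% of changes at 1.3-fold and 55% at 1.5-fold.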

Other observations

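The values and tests in this part were chosen after the results were seen, except the marker pairs and the in-frame shares, which were planned.

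Trav segments were also found joined to Trdj1. Over all libraries, including knockouts that lack a member, 274 such rearrangements were listed. Of them 160 used a Trav15-dv6 member (58.4%, exact Clopper-Pearson interval 52.3 to 64.3%, counting error only). Every Trav listed with Trdj1 carried a dv name, so this is a share among the 10 dv segments, of which 4 are family members. Whether the tables could name Trdj1 for other Trav was not tested. The libraries were primed from Trac, so these counts do not measure how often Tcrd rearranged. In 12 h WT Trav15-1-dv6-1 had 14 of 63, Trav15-2-dv6-2 and Trav14d-3-dv8 11 each, Trav15d-2-dv6d-2 7 and Trav15d-1-dv6d-1 2. Rearrangements ending in Trdj1, Trdv included, stood at 0.0209% ± 0.00532 and 0.0190% ± 0.00637 of Trav-Traj rearrangements in the Trav15d-1-dv6d-1 knockouts and their controls and 0.0148% ± 0.00369 and 0.00750% ± 0.000146 in the Trav15-1-dv6-1 knockouts and theirs (mean ± SD, n = 2, not tested).

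The Traj that V1 segments had joined lay further 3' in DJD and in the Trav15d-1-dv6d-1 knockouts than in their controls. Among V1 rearrangements J3 made up 56.2% ± 2.21 in WT and 74.0% ± 1.05 in DJD, and 49.96% ± 0.316 and 60.1% ± 0.404 in the Trav15d-1-dv6d-1 controls and knockouts, with no overlap between libraries in either case, which chance alone gives in 1 of 3 splits of 2 against 2. In DJD J3 was also higher in V2 (54.6% ± 2.98 and 71.5% ± 0.237) and V4 (11.7% ± 0.0418 and 13.6% ± 0.507). In the Trav15d-1-dv6d-1 controls and knockouts it made up 53.5% ± 0.496 and 52.4% ± 0.488 in V2 and 10.8% ± 0.451 and 11.4% ± 0.814 in V4. In V1 of the Trav15-1-dv6-1 controls and knockouts it went the other way, 50.5% ± 5.00 and 43.6% ± 5.95.

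Across Trav segments, log2 fold changes in DJD and in the Trav15d-1-dv6d-1 knockouts, which have separate controls, had a Pearson r of 0.56 (Spearman rho 0.35) over 82 segments and 0.77 (0.74) over the 23 distal of Trav15d-1-dv6d-1; segments are not independent replicates. For DJD and the Trav15-1-dv6-1 knockouts the same values were 0.64 (0.63) and 0.47 (0.30), and for DJD at steady state and 12 h 0.84 (0.84) and 0.34 (0.33).

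Trav11 or Trav11d with Traj18, the pair of invariant NKT cells, made up 0.0396% to 0.0534% in the steady-state group means, 0.0110% ± 0.00799 in 12 h WT and 0.00561% ± 0.00444 in 12 h DJD. Trav1 with Traj33, the pair of MAIT cells, made up 0.0118% to 0.0879%, 0.00133% ± 0.00188 and 0%, and in DJD 0.0219% ± 0.000926 against 0.0879% ± 0.00512 in WT. Over the product of its V and J shares the first pair stood at 2.63 to 4.62 and the second at 0.906 to 1.61 in the steady-state libraries. Joining in DP cells forms these pairs too, so they do not measure cells outside the gate. In-frame shares were 66.7% to 68.8% in the steady-state group means, 61.6% ± 0.375 in 12 h WT and 62.3% ± 0.417 in 12 h DJD.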
